A study of Drosophila melanogaster with 2 samples.

How the data were processed

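TF ChIP-seq was performed, per the labels, on whole embryos (0 to 24 h) of a transgenic Drosophila strain expressing al fused to eGFP, with an anti-GFP antibody, chromatin sheared by sonication and fragments of 200 to 800 bp. The labels number the libraries as biological replicates 1 and 2 of 1 group. They also name possible control libraries, which were not analysed here. The authors deposited 8 peak lists: a thresholded and an unthresholded ranked list for each replicate, and for the series a thresholded list, a conservative thresholded list and 2 ranked lists. Per the notes deposited with the samples the assembly is dm6, and each list derives from the alignments of 1 replicate or of both. The thresholded lists derive from 1 further file whose role is not stated. The aligner, the peak caller, their versions and the filters are not given in the sources used here.

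The deposited signal value of each peak is the authors' own enrichment measure, and its scaling is not given in the sources used here, so it was used to describe and rank peaks within a list. Signals of the replicates were set side by side from the ranked list that holds a value from each. The input of each column was identified from matching values, since 63464 of 126637 first values occurred in the replicate 1 list and none of them in the replicate 2 list, and 76557 second values occurred in the replicate 2 list and none in the replicate 1 list. The authors' −log10 q value was used to count peaks: in the series' thresholded list 950 peaks (24.7%) had a q above 0.05 of their own. The deposited score is the irreproducible discovery rate (IDR, the rate of peaks that disagree between inputs) scaled to at most 1000, a value that 84.5% of these peaks hold, so it could not rank them. From the values, every thresholded peak has a global IDR of at most 0.01 in its ranked list. Of the 3848 peaks, 3177 (82.6%) have a width of 330 bp. No read counts are in the lists used here, so the depth per sample is unknown, and no interval for a signal can be given. Intervals on shares cover counting error over peaks only.

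Peak positions were set against the release 6 genome sequence and the Ensembl release 115 annotation (BDGP6.54), which share the coordinates of dm6. Analyses used the 7 chromosome arms X, 2L, 2R, 3L, 3R, 4 and Y, which hold 3822 of the 3848 peaks. A summit was classed as promoter within 500 bp of the TSS of a protein-coding transcript, and otherwise as 5' UTR, CDS, 3' UTR, intron or intergenic in that order. The promoter share was compared with 1000 random placements of as many points on the same arms. Replicate lists were compared with bedtools 2.31.1 at a minimum overlap of 1 bp, beside 100 random placements. A gene was called covered when a summit lay inside it or within 2 kb, and each of 20 gene lists was compared with 10000 random lists matched on gene length in 20 bins, with Benjamini-Hochberg adjustment over the lists. The 18 motifs were searched on both strands within 100 bp of each summit and in 1 equal window per peak centred 1 kb to the left or right, by the exact two-sided McNemar test with Benjamini-Hochberg adjustment over the motifs, and all 2080 6-mers likewise. Differences in median log2 signal were tested with 100000 permutations, and X against autosomes with an exact binomial test. All tests were two-sided. Ribosomal protein, proteasome, chemoreceptor and cuticle genes were taken by symbol pattern, and all other lists by name, with 3 symbols (h, Dl and dys) read as their current names. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

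The lists, motifs, tests and alternatives were fixed before the data were examined, as was the rule for the genes to name. The rule takes al, the gene nearest to each of the 10 strongest peaks, the 5 strongest peaks with no protein-coding TSS within 1 kb, up to 4 covered members of each list with the strongest peaks and up to 2 uncovered members, and the 10 6-mers with the largest ratios. A gene that the rule takes is not reported here. Alternatives were the conservative list, each replicate's own list in place of the series' list, other windows, overlaps and gene assignments, no length matching, ranked peaks under the threshold as background, and random windows matched on GC content (in bins of 2%) and promoter class. A global IDR of 0.0001, the removal of peaks within 250 bp of a stronger one and the addition of ranked peaks absent from the thresholded list were chosen after seeing the data.

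Several of the statistics were tested on simulated data. For the promoter share, a planted share of 55.9% over 3822 points was recovered as 55.9%, and 2 of 100 unplanted sets passed the threshold. For gene list coverage over 13968 genes, 100 of 100 simulated lists of 50 genes raised by 30 percentage points were called and 3 of 100 unraised ones, but of lists of 12 genes raised by as much only 58 of 100 were called, before adjustment. For motif enrichment only the motif search was run on planted sites. It found all 216 of the 3822 windows given a DRE, an outcome fixed by construction that does not test the enrichment statistic. For 6-mer enrichment, 0 of 2080 6-mers were called between randomly swapped windows. For the strength relation over 3822 peaks, 3 of 100 unshifted splits were called.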

Results

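Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the protein Aristaless sits on the genome of Drosophila melanogaster embryos. Aristaless, the product of the gene al, is a paired-class homeodomain transcription factor known for its part in patterning the tips of the legs, the antennae and the wings. The flies carried al fused to eGFP, and the tagged protein was pulled down with an antibody against GFP from whole embryos aged 0 to 24 h. The data form 1 group of 2 biological replicates, so there is no contrast between groups. The questions the data address are how far the replicates found the same sites, where those sites lie, which genes they lie at and which sequences they hold. The series' thresholded list, made from both replicates, held 3848 peaks with a median signal of 90.0, and it is the main set below. A conservative list held 3493 peaks. Replicate 1 alone gave 2987 peaks with a median signal of 67.4, and replicate 2 alone gave 2114 peaks with a median signal of 56.9. The signal of a peak is the authors' own value, and the read depth behind it is unknown here. All positions are on release 6 of the fly genome (dm6).

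The strongest sites were found in both replicates, and most of the disagreement lay among the weak ones. Of the replicate 1 peaks, 1849 of 2987 overlapped a replicate 2 peak by at least 1 bp, or 61.9% (95% Wilson interval 60.1 to 63.6). Of the replicate 2 peaks, 1830 of 2114 overlapped a replicate 1 peak, or 86.6% (85.0 to 88.0). Randomly placed lists overlapped for 0.919% ± 0.175 (SD over 100 placements) of the replicate 1 peaks and 1.35% ± 0.255 of the replicate 2 peaks. When each list was split by signal into 4 equal groups, 98.4% of the strongest group of replicate 1 peaks and 24.2% of the weakest overlapped a replicate 2 peak. For replicate 2 these shares were 99.8% and 62.4%.

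Peak by peak, across all 126637 entries of the ranked list, Pearson's r between the replicates' signals was 0.891, or 0.379 on log2 values, and Spearman's rho was 0.257. Across the 3493 conservative peaks r was 0.960, or 0.886 on log2 values, and rho 0.804, but these peaks were selected by the authors for their agreement between the replicates, so high values are built into that set. These coefficients are across peaks, which are not independent replicates. The peak near CG14100 on 3L carried a signal of 1128 in replicate 1 and 964 in replicate 2, and the intronic peak of CG11050 carried 1303 and 757.

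**Figure D1:**
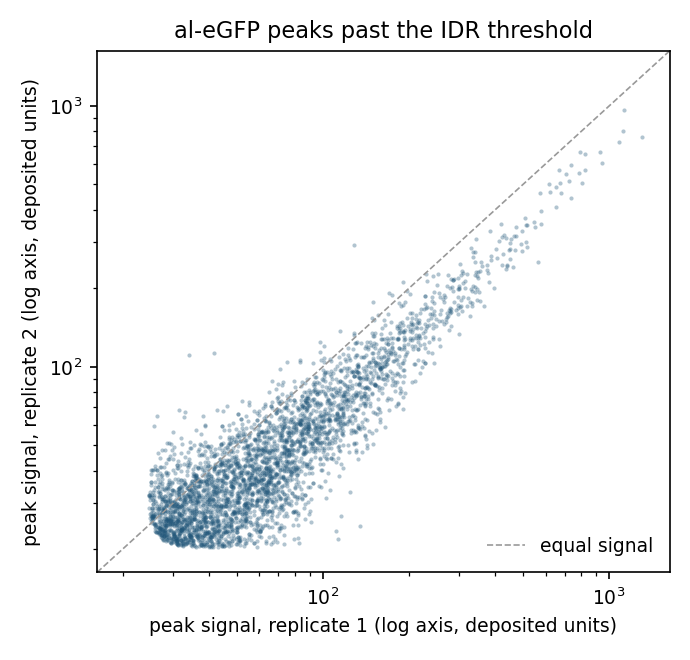
Signal of each of the 3493 conservative al-eGFP peaks in replicate 1 (x axis) and replicate 2 (y axis), in the authors' units on log axes, with 1 point per peak and a dashed line where both are equal. The points narrow towards the strong end, and r over these peaks is 0.960.

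Aristaless peaks were concentrated at promoters. Of the 3822 summits on the 7 chromosome arms, 1958 lay within 500 bp of the transcription start site (TSS) of a protein-coding gene, or 51.2% (95% Wilson interval 49.6 to 52.8), which was 4.47 times the 11.5% ± 0.510 (SD) of randomly placed points. In the replicates' own lists the promoter share was 54.4% and 57.4%, a mean of 55.9% ± 2.14 (SD, n = 2 replicates). Introns held 33.4% of the summits (random points 39.2%), intergenic sequence 12.8% (30%), coding sequence 1.28% (13.8%), 3' UTRs 0.837% (4.64%) and 5' UTRs 0.445% (0.788%). The median distance from summit to nearest TSS was 444 bp, with 20.5% of the summits within 100 bp and 1454 beyond 1 kb. The promoter share differed from that of random points with a two-sided permutation p of 0.001, the smallest that 1000 placements can give. No library of untagged embryos or of another tagged protein was analysed. Aristaless binding therefore cannot be told apart here from a general signal at promoters.

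**Figure D2:**
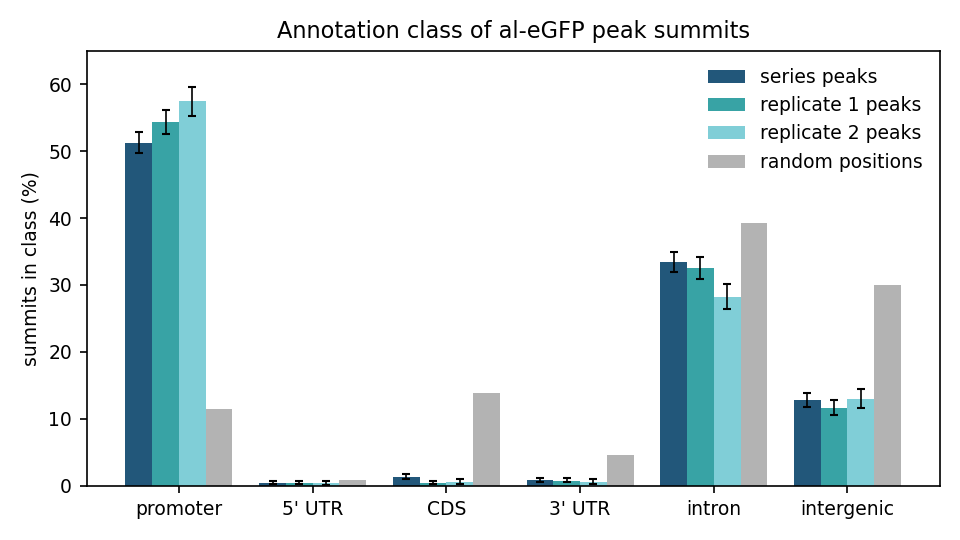
Share of peak summits (y axis, %) in each annotation class (x axis) for the series' list and each replicate's list, with 95% Wilson intervals as error bars, beside random positions in grey. Promoters held 51.2% of the series' summits and 11.5% of random positions, and coding sequence held 1.28% and 13.8%.

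Of the 10 strongest peaks, 6 lay at promoters, 3 in introns and 1 in intergenic sequence. The strongest, with a signal of 2083, spanned 3L from 19590448 to 19590793 and had its summit 97 bp from the TSS of CG14100. Promoter peaks among the 10 also stood at mRpL41, a mitochondrial ribosomal protein gene (2R, 15217581 to 15217926, signal 1915), at Ugalt, a UDP-galactose transporter gene (X, 2703707 to 2704049, signal 1795), at Tcs5 (3L, 5139343 to 5139653, signal 1572), at CG7601 (3R, 29736692 to 29737007, signal 1464) and at eIF6, which encodes a ribosome biogenesis and translation factor (2R, 23850256 to 23850560, signal 1381). The eIF6 peak lay inside the gene ytr and was also the strongest peak within 2 kb of gbb. Intronic peaks stood in CG11050 (2L, 6612539 to 6612886, signal 2051), in Adf1, a gene for a transcription factor (2R, 6662905 to 6663219, signal 1431), and in the overlapping genes HmgD and HmgZ for chromosomal high-mobility-group proteins (2R, 21703163 to 21703622, signal 1347). The peak nearest to CG4004 was intergenic, 5092 bp from that gene's TSS (X, 12751193 to 12751593, signal 1528).

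Away from promoters, the 5 strongest peaks with no protein-coding TSS within 1 kb were those of CG11050 and CG4004 and 3 intronic peaks. The first of these lay in Trl, the gene for GAGA factor (3L, 14759343 to 14759698, signal 1309), 1534 bp from its nearest TSS. The others lay in CG32772 (X, 4910223 to 4910527, signal 1155) and CG3726 (X, 5918786 to 5919056, signal 891). The CG11050 peak held the homeodomain core TAATTA within 100 bp of its summit, and the other 4 did not. Among the 10 strongest peaks of any class, those of CG11050, Tcs5, CG7601 and Adf1 held the core and the rest did not.

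Ribosomal protein genes were the one group among 20 lists fixed in advance that carried more peaks than matched genes past the threshold. The lists for Dpp, EGFR and Notch signalling and for the proteasome also lay above matched genes, without passing. Of 92 ribosomal protein genes, cytoplasmic ones by symbol, 62 had a summit inside the gene or within 2 kb, or 67.4%, where random lists of the same gene lengths had 26.1% ± 4.48 (SD; adjusted p = 0.001, two-sided permutation test). Among them were RpL32 (strongest signal 398), RpL3 (371) and RpS27 (360), although the RpL3 peak lay 4777 bp from the TSS of that gene. RpS7 and RpL13A had none in the series' list, although the replicate 1 list held a peak at RpS7 (signal 60.3). The coverage was 63.0% with the replicate 1 list and 51.1% with the replicate 2 list. Over all 13968 protein-coding genes, 4656 were covered, or 33.3%.

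Chemoreceptor, cuticle protein and paired-class homeobox genes carried fewer peaks than matched genes. Of 179 chemoreceptor genes of the odorant, gustatory and ionotropic families, 12 were covered, or 6.70% against 31% ± 3.36 (adjusted p = 0.001, permutation test), among them Or85f (signal 323), Ir94c (176), Ir68b (144) and Gr89a (138), whereas Or85c and Gr93c were not. Of 95 cuticle protein genes 7 were covered, or 7.37% against 25.7% ± 4.42 (adjusted p = 0.00133, permutation test). Cpr76Ba (signal 271) and Cpr73D (131) led them, Cpr67Fb and Cpr67Fa2 shared a peak of signal 75.3, and TwdlV and Cpr97Eb had none. Of the 25 paired-class homeobox genes, the family of al itself, 4 were covered, or 16% against 46.2% ± 9.68 (adjusted p = 0.00800, permutation test). These were otp (signal 192), Vsx1 (89.7), al (50.6) and OdsH (50.2), and prd and gsb had no peak. None of the 179 chemoreceptor genes and none of the 95 cuticle protein genes had a summit within 500 bp of its own TSS. All 3 calls held with each replicate's own list, with 5 and 9 chemoreceptor, 2 and 4 cuticle protein and 1 and 3 paired-class genes covered by the replicate 2 and replicate 1 lists. For ribosomal proteins and chemoreceptors the permutation p before adjustment, 1e-04, is the smallest that 10000 random lists can give. The random lists drew genes independently, whereas neighbouring members of a list can share a summit, as Cpr67Fb and Cpr67Fa2 do, or lack one together. The SDs and p-values may therefore understate the spread, and how far list members cluster was not assessed. The call on the paired-class genes was lost without matching on gene length (adjusted p = 0.291, Fisher's exact test), and in permutation tests with only summits within 500 bp of the gene's own TSS (4% against 23.7%, adjusted p = 0.145) or a global IDR of 0.0001 (4% against 23.9%, adjusted p = 0.150). That on the cuticle genes was lost when a peak was given to its nearest TSS within 10 kb alone (4.21% against 12.5%, adjusted p = 0.0890, permutation test).

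The lists for signalling pathways did not differ from length-matched genes past the threshold, with adjusted p between 0.216 and 1 in permutation tests. Dpp signalling had the highest share, with 9 of 13 genes (69.2% against 45%, adjusted p = 0.216, permutation test), led by the BMP ligand gene gbb (signal 1381), the co-Smad gene Med (782), shn (244) and sog (234), whereas put and sax had no peak. The gbb peak is the one at the eIF6 promoter, the Med peak lay 5125 bp from the TSS of Med, and 0 of the 13 genes had a summit within 500 bp of their own TSS (23.2% in matched lists), which turned the direction. For EGFR signalling 8 of 13 genes were covered (61.5% against 48.0%), led by the ligand gene spi (365), aos (261), Krn (178) and sty (166), with none at Egfr or rho. For Notch signalling 7 of 16 were covered (43.8% against 38.6%), led by mam (343), E(spl)m8-HLH (343), E(spl)m3-HLH (184) and neur (155), with none at Delta or Ser. The E(spl)m8-HLH peak lay at another gene's promoter, 2278 bp from the TSS of E(spl)m8-HLH. For Wnt signalling 7 of 15 were covered (46.7% against 49.5%), led by fz (228), arr (200), nkd (165) and Wnt6 (136), with none at wg or dsh. For Hedgehog signalling 3 of 11 were covered (27.3% against 41.1%), namely boi (57.6), ptc (55.0) and hh (33.5), with none at smo or ci. None of these 3 peaks was in a replicate's own list, and the count was 1 with the replicate 1 list and 0 with the replicate 2 list. The Wnt count was 4 with the replicate 2 list.

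The lists of patterning genes did not pass the threshold in either direction. The list for the legs, antennae and wings, where al is known to act, had 9 of 28 genes covered (32.1% against 49.8%, adjusted p = 0.216, permutation test). Its strongest peaks were at Dll, the distal limb selector gene (signal 213, at the promoter on 2R, 24814670 to 24814752), hth (182), bab2 (119) and dan (86.5), and exd and ap had none. Among gap and head gap genes only cnc was covered, 1 of 11 (signal 68.3 in replicate 1's own list), with none at hb or Kr (adjusted p = 0.204, permutation test). Among pair-rule and segment polarity genes 3 of 18 were covered (adjusted p = 0.178, permutation test), nkd, ptc and hh, with none at eve or ftz. Of the 8 Hox genes, Abd-B (88.3), Antp (67.5) and Ubx (56.6) were covered and lab and pb were not (adjusted p = 0.683, permutation test). The Ubx and dan peaks lay at promoters of other genes, 78458 and 8945 bp from the named gene's own TSS. Within 500 bp of their own TSS, 0 of the 8 Hox genes had a summit. With the replicate 1 list alone the appendage list, 4 of 28 (adjusted p = 0.0180), and the pair-rule list, 1 of 18 (0.0357), passed the permutation test on the low side, as did the pair-rule list in the conservative set (0.00840). With peaks given to the nearest TSS within 10 kb the pair-rule list turned to the high side without passing, at 6 of 18 (33.3% against 25.9%). With the replicate 2 list the appendage count was 4, the gap gene count 0 and the Hox count 1.

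Marker lists for tissues did not differ from length-matched genes past the threshold, with adjusted p between 0.638 and 1 in permutation tests. Neuronal genes were covered in 6 of 14 cases, with the strongest peaks at elav (signal 581) and nSyb (231) and a shared intronic peak at ChAT and VAChT (118), and none at Syt1 or brp. Glial genes were covered in 2 of 9 cases, moody (571) and pnt (155), and not at repo or gcm. Muscle genes were covered in 5 of 13 cases, led by the muscle regulator gene Mef2 (815), sls (260), Mlc2 (78.6) and Act57B (66.8), with none at Mhc or Mlc1. Haemocyte genes were covered in 3 of 11 cases, ush (76.1), lz (57.7) and srp (52.4), with none at gcm or Pxn, and tracheal genes in 4 of 9, bnl (116), dysf (103), trh (87.5) and serp (76.2), with none at btl or vvl. A stronger peak inside ush (signal 1736) is in the series' ranked list but absent from the thresholded list. Gut and fat body genes were covered in 4 of 11 cases, bin (219), grn (60.2), srp and svp (46.6), with none at GATAe or hkb. With the replicate 1 and replicate 2 lists the haemocyte count was 1 and 0 and the gut and fat body count 1 and 1, and with the replicate 2 list the neuronal count was 2 and the muscle count 3. Proteasome genes were covered in 16 of 48 cases (33.3% against 27.7%, adjusted p = 0.638, permutation test), led by Rpn5 (525), Prosalpha4 (190), Prosbeta6 (174) and Rpn3 (156), with none at Prosalpha3T or Prosbeta2R2. The strongest peaks of Mef2, Mlc2, nSyb, Rpn5 and Prosbeta6 lay at promoters of other genes. Their distances from the named gene's own TSS were 1053, 3787, 1846, 2271 and 1979 bp. Counting only summits within 500 bp of the own TSS, 2 of 13 muscle and 1 of 14 neuronal genes were covered.

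**Figure D3:**
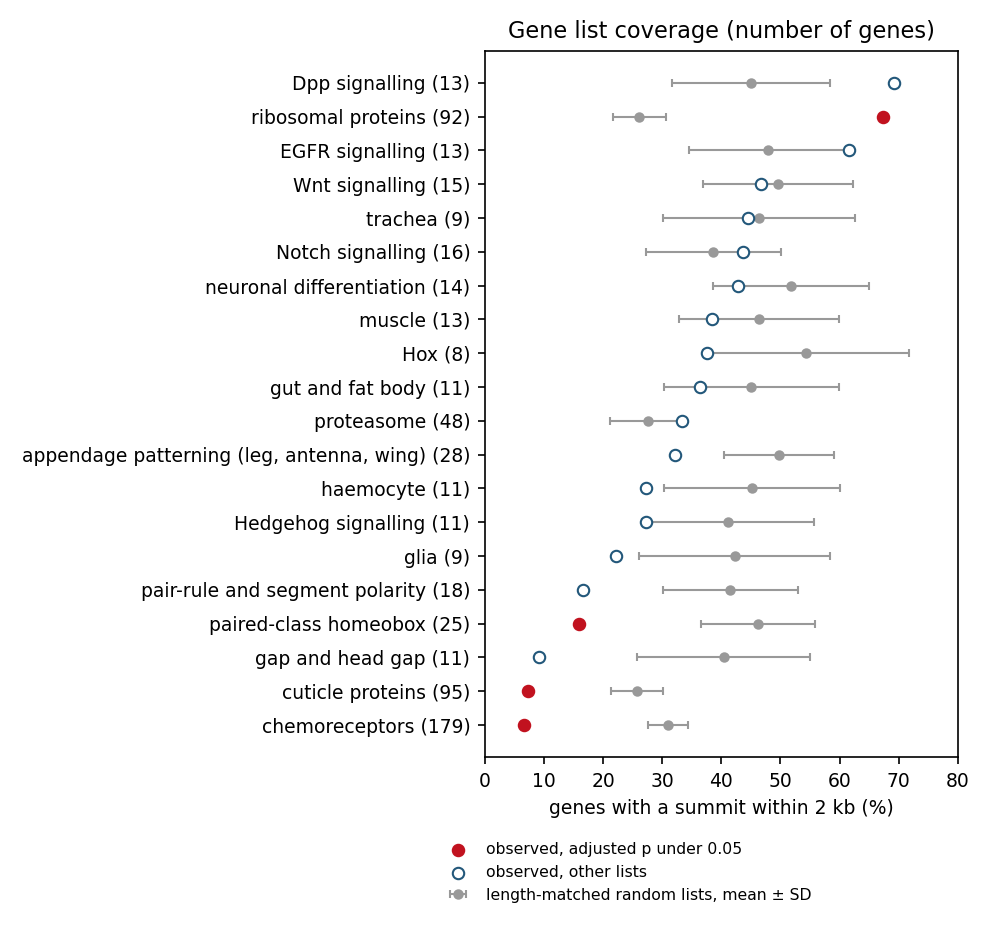
Share of genes with a summit inside or within 2 kb (x axis, %) for each of the 20 lists (y axis, number of genes in parentheses), beside the mean and SD of 10000 length-matched random lists in grey. Filled red points passed an adjusted p of 0.05, namely ribosomal proteins above the random lists at 67.4% and chemoreceptors, cuticle proteins and paired-class homeobox genes below them.

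The DRE and Motif 1, known as core promoter elements, had the largest ratios of 18 motifs at Aristaless summits when compared with the flanks. The DRE (TATCGATA), bound by DREF, occurred within 100 bp of 4.37% of the summits and in 0.523% of equal windows centred 1 kb away, a ratio of 8.35 (adjusted p = 8.16e-29, two-sided exact McNemar test). M1BP's Motif 1 (GGTCACACT) stood at 1.41% and 0.262%, a ratio of 5.40 (adjusted p = 1.20e-07, exact test). The DRE lay at 8.22% of the 1958 promoter summits and 0.322% of the other 1864, and Motif 1 at 2.45% and 0.322%, differences that were not tested. Against random windows matched on GC content and promoter class the ratios were 2.83 for the DRE and 1.80 for Motif 1, below the 2.05 of the GAGA factor site. Against ranked peaks under the threshold they were 3.21 and 2.70, below the 4.83 of the paired-class dimer with a 2-bp spacer. The DRE ratio was 12.5 with the replicate 2 list alone, and the Motif 1 ratio was 3.45 with the replicate 1 list alone. The order of the pair changed at a global IDR of 0.0001 (DRE 5.5, Motif 1 13) and within 250 bp of the summit (DRE 5.16, Motif 1 6.48).

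Sites for paired-class homeodomains were more frequent at summits than in the flanks, by smaller ratios. The core TAATTA lay within 100 bp of 17.7% of the summits and in 11.7% of the flanking windows, a ratio of 1.51 (adjusted p = 1.20e-12, exact McNemar test). The palindromic dimers that paired-class proteins are known to bind had ratios of 2.22 with a 2-bp spacer (TAATNNATTA, 2.90% and 1.31%, adjusted p = 5.63e-06) and 1.73 with a 3-bp spacer (TAATNNNATTA, 2.98% and 1.73%, adjusted p = 0.00129, exact tests). At promoter peaks the ratios were 1.99 for the core, 3 for the 2-bp dimer and 2.14 for the 3-bp dimer, all past the threshold. In the other 1864 peaks none passed, at 1.17, 1.56 and 1.41 (adjusted p = 0.160, 0.222 and 0.309, exact tests), and the difference between promoter and other peaks was not tested. The 3-bp dimer ratio was 3.70 with the replicate 2 list alone, and its call was lost within 50 bp of the summit (1.61, adjusted p = 0.0717, exact test). The summits were richer in A and T than their flanks, with a GC content of 36.2% against 43.1%, and this gap was wider at promoter peaks (35.7% against 45%) than at other peaks (36.8% against 41%). Against random windows of the same GC content the core had a ratio of 1.01 (adjusted p = 0.901, exact McNemar test), the 2-bp dimer 1.42 (0.0409) and the 3-bp dimer 1.15 (0.454). Against ranked peaks under the threshold, whose GC content was 47.1%, the ratios were 2.07 for the core (adjusted p = 1.03e-29, exact McNemar test), 4.83 for the 2-bp dimer (3.02e-14) and 2.65 for the 3-bp dimer (4.75e-08).

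Of the other 13 motifs, 3 were rarer at summits than in the flanks. These were the CA repeat (ratio 0.655, adjusted p = 1.87e-05), the E-box CACGTG (0.602, adjusted p = 0.00174) and the Polycomb recruiter site PHO (0.854, adjusted p = 0.00267, exact tests). The CACGTG call was lost with the shorter lists of replicate 1 (0.711, adjusted p = 0.0964, exact test) and replicate 2 (0.692, adjusted p = 0.105), and with GC-matched windows neither the E-box (0.202) nor the CA repeat (0.650) passed. The GAGA factor site (ratio 0.896), Bicoid-type homeodomain site (0.887), Zelda site (0.865), GATA (0.993), AP-1 (0.859), E-box CAGCTG (0.848), Grainyhead (0.636), Ets (1.27), POU octamer (0.900) and TCF (0.843) did not pass the adjusted threshold of 0.05. Several passed on the low side under alternatives: the GAGA factor site (0.5) and CAGCTG (0.681) within 50 bp of the summit, both at a global IDR of 0.0001 (0.545 and 0.658), CAGCTG in the conservative set (0.770), with the absent peaks added (0.804) and against ranked peaks under the threshold (0.707), Zelda at that IDR (0.647) and against those peaks (0.770), and the Bicoid-type site (0.783) and POU octamer (0.829) within 250 bp. The sides of the flanks were drawn anew for each peak list. With the absent peaks added, CAGCTG stood at 8.29% of summits (main list 8.32%) and 10.3% of flanks (9.81%). Ratios to the flanks can therefore shift between lists with the draw alone. GATA turned to 1.22 against ranked peaks under the threshold, and within 250 bp the GAGA factor site turned to 1.59, CAGCTG to 1.12 and the CA repeat to 1.12, all past the threshold. The GAGA factor site and the E-box CAGCTG turned to ratios of 2.05 and 1.45 against GC-matched windows, both past the threshold. Against the same windows TCF (0.656, adjusted p = 0.00785, exact test) and the Bicoid-type site (0.817, adjusted p = 0.0482) passed on the low side.

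**Figure D4:**
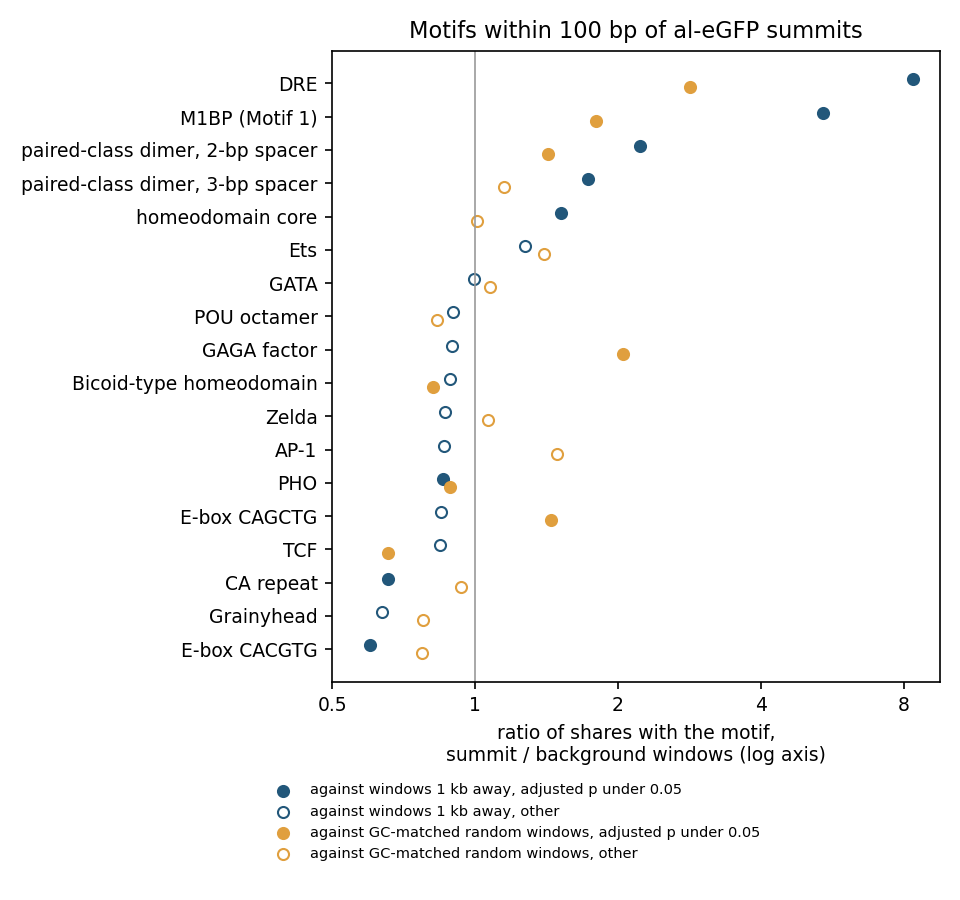
Ratio of the share of summit windows with each motif to that of background windows (x axis, log scale) for 18 motifs (y axis), against windows 1 kb away in blue and against GC-matched random windows in orange, filled where the adjusted p was under 0.05. The DRE stands highest at 8.35 and 2.83, and the homeodomain core falls from 1.51 to 1.01.

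A search over all 2080 6-mers, with no motif chosen in advance, found 457 more frequent and 931 less frequent at summits than in the flanks past an adjusted p of 0.05. The 10 with the largest ratios were CGATAG (2.32), ACACTG (2.28), ACCCTA (2.21), TAGCTA (2.18), TATCGA (2.13), AGTGTA (2.11), CGCTAG (2.07), ACTGTA (2.07), ACAGTG (2.07) and ATATTA (2.06). TATCGA is part of the DRE. TAATTA ranked 136 among the 457. Against GC-matched windows 221 were more frequent and 229 less frequent, and the 10 named here all stayed above 1 past the threshold, from 1.24 for ATATTA to 2.77 for ACAGTG.

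**Figure D5:**
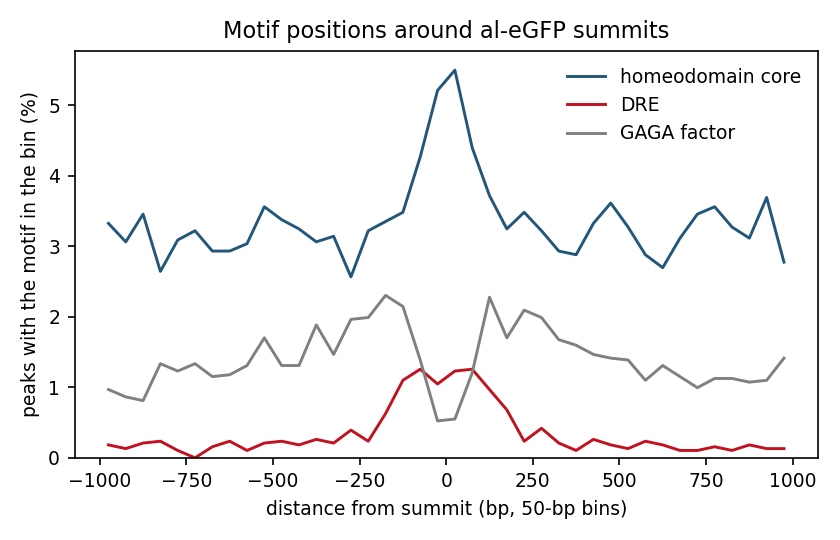
Share of peaks with a motif (y axis, %) in each 50-bp bin by distance from the summit (x axis, bp) for the homeodomain core, the DRE and the GAGA factor site. The core reaches 5.49% in the bin just right of the summit, and the GAGA factor site falls to 0.523% just left of it with 2.30% at -175 bp and 2.28% at 125 bp.

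Promoter peaks were stronger than the others. Their median signal was 101 against 81.8, a log2 difference of 0.30 (p = 1e-05, the smallest that 100000 permutations can give, two-sided). The log2 difference was 0.18 in the replicate 2 list and 0.16 in the replicate 1 list, both past the threshold. From the weakest to the strongest of 4 equal groups the promoter share was 38.3%, 52.1%, 52.7% and 61.8%. In the same order the homeodomain core lay at 15.1%, 17.8%, 18.1% and 19.98% of the summits. Its share of the flanks was 12.4%, 11.6%, 10.6% and 12.2%. The 95% intervals for the summits ran from 12.9 to 17.5 in the weakest group and from 17.6 to 22.6 in the strongest. These core shares pool promoter with other peaks, and the trend was not tested. Peaks with the homeodomain core did not differ in signal past the threshold from those without it, either at promoters (102 against 100, permutation p = 0.657) or elsewhere (88.5 against 80.4, log2 difference 0.14, permutation p = 0.0682). Elsewhere the log2 difference passed in the conservative set (0.16, permutation p = 0.0247) and with the peaks absent from the thresholded list added (0.15, permutation p = 0.0405).

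The X chromosome carried more Aristaless peaks per length than the autosomes. It held 770 summits, or 32.8 per Mb of sequenced bases (95% interval 30.8 to 34.9), against 28 per Mb over 2L, 2R, 3L and 3R, a ratio of 1.17 (exact binomial p = 1.15e-04). The autosomal arms ranged from 26.7 per Mb on 2R to 29.5 per Mb on 3L. Chromosome 4 held 3 summits and Y held 2, or 2.25 and 0.587 per Mb. With the replicate 1 list these counts were 8 and 0, and with the replicate 2 list 1 and 2. How well reads map on chromosome 4 and Y was not assessed. The ratio of X to autosomes was 1.14 in each replicate's own list.

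At the al gene itself (FBgn0000061, 2L, 378112 to 387439, plus strand) the series' list placed a weak peak on the promoter. It spanned 377644 to 377973 with its summit 303 bp from the al TSS, and its signal of 50.6 ranked 3496 in the list. No peak overlapping it was in either replicate's own thresholded list. Within 50 kb of al there were 5 peaks, the strongest of which lay at the promoter of AP-2alpha, a transcription factor gene (414698 to 415027, signal 270). Others lay at a further AP-2alpha promoter (65.8), at the promoter of CG11885 (50.6) and 1024 bp from a TSS of ex (82.4). The median over protein-coding genes was 4 peaks, and 42.1% of genes had at least 5. With the replicate 2 list alone the count was 2, and with the conservative set it was also 2. The labels call the tagged strain an insertion, so extra copies of the al region may be present. Their effect on the peaks and signals here was not assessed.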

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

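The tests in this part, counts of peaks that the comparisons above do not use, were chosen only after the lists were seen. The series' ranked list holds 147 peaks that pass a global IDR of 0.01 and yet are absent from the thresholded list, 100 of them on the chromosome arms, of which 57 on 3R. The strongest lies inside ush, 1408 bp from the TSS of cbt (2L, 480938 to 481254, signal 1736), and the next lie at Lk6 (3R, 11760909 to 11761188, signal 969), CG18428 (3R, 24109014 to 24109372, signal 952), larp (3R, 28326464 to 28326733, signal 714) and in trx, the gene for a Trithorax-group protein (3R, 14283757 to 14284017, signal 592). Grouped at distances of up to 10 kb, the 100 form 53 clusters of at most 6 peaks. The same kind of gap is present in the replicate lists, with 99 peaks for replicate 1 and 113 for replicate 2. The thresholded list also holds 26 peaks on contigs outside the 7 chromosome arms, which entered none of the comparisons by gene, class or motif.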

How the results depend on the processing

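The tests with an IDR of 0.0001, without shoulder peaks (a stronger summit within 250 bp) and with the absent peaks were chosen only after the results were seen. Of 490 alternative values for 52 results, 437 were counted as unchanged. Among these were all values for the promoter share (ratios from 3.05 to 7.55), the X-to-autosome ratio (1.14 to 1.21) and the lists of ribosomal protein and chemoreceptor genes. That count includes 50 changes of direction where neither value passed a test. It also includes the values at a global IDR of 0.01, which were fixed in advance because that setting removed no peak. Merging summits within 100 bp also removed no peak and was counted likewise. The score was too saturated to be run as a measure of strength. At an IDR of 0.0001 the peak count fell to 1481. Replicate overlap of 61.9% and 86.6% moved to 54.0% and 76.1% under 50% reciprocal overlap, to 59.1% and 83.4% for summits within 100 bp, to 77.4% and 79.0% at equal list lengths, and the second to 92.7% at an IDR of 0.0001. The replicate correlation of 0.891 was 0.960 past the threshold and 0.379 on log2 values. Against GC-matched windows the homeodomain core fell to 1.01 and the 6-mers to 221 more and 229 less frequent. In non-promoter peaks the log2 signal difference by core passed at 0.16 (conservative set) and 0.15 (absent peaks added). Near al the count of 5 was 2 in the conservative set, 1 at an IDR of 0.0001, 1 within 20 kb and 12 within 100 kb, and 2 to 4 without replicate 1 or 2. Reversed ratios were the GAGA factor site (1.59 in windows of 250 bp, 2.05 GC-matched), CA repeat (1.12, 250 bp), GATA (1.22 against peaks under the threshold), CAGCTG (1.12, 250 bp; 1.45 GC-matched) and CACGTG (1.06, 250 bp). Among single lists, 4 values lost and 3 gained a call, and among other motifs 6 lost and 13 gained one. The cause was not tested. No paired analysis was possible because there is 1 group. The depth is unknown, so its limits are too.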

Other observations

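Chosen only after results were seen were the tests of the rank of the core, the intervals of the ranks (added once the ranks were known), the comparison with distance-matched points (added once the share of divergent promoters was known) and the values on noncoding genes, the GAGA profile and weak peaks. The rank of the dimer with a 2-bp spacer was tested once its ratio of 1.42 was known. Of the summits, 73 lay within 500 bp of an annotated transposable element, where random placements gave 318 ± 17.4 (SD). The random points could fall on any sequenced base, repeats included, and how well reads map there was not assessed. The shortfall at these elements therefore cannot be read as avoidance. Small nuclear RNA genes had 3 such summits (random 0.900 ± 0.847), small nucleolar RNA genes 11 (5.17 ± 2.27), tRNA genes 9 (7 ± 2.64) and pseudogenes 8 (14.4 ± 3.86). The GAGA factor site was found at 0.523% and 0.549% of peaks in the bins on either side of the summit against 2.30% at -175 bp and 2.28% at 125 bp. Against GC-matched windows, the 6-mers with the largest ratios were ACAGTG (2.77), ACACTG (2.17), CCAGGG (2.13), CGATAG (2.09) and CAGTGC (2.07), none of them a homeodomain core. Of the 110 peaks with a signal under 20, 109 had a stronger listed peak within 250 bp, against 29 of the 3738 others.

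The homeodomain core was 1.51 times as frequent at summits as in the flanks. Local AT content is a candidate explanation that the values allow. Against GC-matched windows the ratio was 1.01 (95% interval over 1000 resamples 0.915 to 1.11). Random genomic windows chosen for the GC content of the peaks, with no peak in them, gave 1.59 over their own flanks. An excess in those windows follows from that choice, so it illustrates the explanation and does not test it. The GC content of those flanks was not compared with that of the peak flanks. The core ranked 35 (interval 23 to 36) among the 36 6-mers made only of A and T, whose median ratio to the flanks was 1.78. Some that ranked above it hold its part TAAT (ATTA on the other strand), such as ATATTA (2.06) and ATAATA (1.90). Others, such as TTTAAA (2.06), do not. Recognition of TAAT would raise the competitors that hold it too. The rank therefore argues at most against the full TAATTA as the main source of the excess, and not against recognition of TAAT. That rank was not computed for random windows and pools promoter with other peaks. Recognition of TAAT, or of the core at a minority of sites, therefore stays open. The dimer with a 2-bp spacer kept a ratio of 1.42 against GC-matched windows and ranked 13 of 136 A/T sites of that form. The interval of that rank ran from 1 to 99, so a preference for this dimer and a preference for any AT-rich site cannot be told apart here. The dimer with a 3-bp spacer, for which no prediction was written, had a ratio of 1.15 and ranked 80 of 136 (interval 8 to 134) among sites of its own form. With 1 group, no contrast between conditions was available to test these explanations further.

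Ribosomal protein genes were covered in 67.4% of cases and paired-class homeobox genes in 16%. Peaks belonging to neighbouring genes are argued against as the whole cause for the ribosomal genes, since 54.3% of them had a summit within 500 bp of their own TSS, 37.9 percentage points above lists matched on length and on neighbouring TSSs (16.5% ± 3.74 SD, permutation p = 1e-04, the smallest possible), while for the paired-class genes that comparison gave 4% against 16.8% (p = 0.0977) and left neighbours open. For the paired-class genes, the peaks absent from the thresholded list are also argued against. With them added 4 of the 25 genes were covered, as before (expected 46.7%, permutation p = 0.00160). Only 100 of the absent peaks lay on the arms, so a large change was unlikely from the outset. A general signal at active promoters that any GFP-tagged protein might give stays open, because the samples analysed include 0 libraries of untagged embryos or of another tagged protein, and so Aristaless binding and such a signal cannot be told apart for these gene groups.

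A hypothesis formed and tested on the same data was that Aristaless peaks may favour promoters shared by head-to-head gene pairs. Of the 1958 promoter summits, 772 lay within 500 bp of divergent TSSs on both strands, or 39.4% (95% Wilson interval 37.3 to 41.6), against 10.6% ± 0.725 (SD) of random promoter points (permutation p = 0.005, the smallest that 200 draws can give). Summits lay upstream of the nearest TSS in 84.9% of cases, which by itself raises the chance of meeting a partner, and points placed at the same distances from random TSSs reached 25.1% ± 1.03. The observed share was 1.57 times that (permutation p = 0.005), which argues against position as the whole cause. Whether such pairs are simply more active in embryos was not tested, since no expression data were used here.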
